A study of Rattus norvegicus with 18 samples.

How the data were processed

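Adult Long-Evans rats, an outbred laboratory strain, either stayed in the home cage (naive) or were trained in inhibitory avoidance, a task in which the animal learns to stay out of a place where it received a foot shock. Trained rats were killed 1 h or 6 d later. Tissue of the dorsal hippocampus (dHC) and of the prelimbic cortex (PL), a medial prefrontal area, was punched from frozen brain, and RNA of 5 rats was combined in each pool. Each of the 6 groups (2 regions, 3 conditions) held 3 pools, so that 18 libraries were compared. Per the labels' protocols, libraries were made from 200 ng of total RNA with a stranded kit selecting polyadenylated RNA, amplified by 12 cycles of PCR and read in pairs of 150 nt. The labels describe the pools of a group as independent. They number the libraries in consecutive blocks by group and name no batch or day, so the order of handling could not be separated from the groups.

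The deposited values are whole-number counts of reads per Ensembl gene, one table per library with 32662 gene rows and 5 rows for reads given to no gene. The submitters' processing notes name the rat assembly Rnor_6.0, Picard 1.126, bedtools 2.17.0 and DESeq2, with no role for each. The aligner, the counting program, the annotation release and the strand setting of the counting are not given in the sources used here. Genes that overlap another gene, lie antisense to one or have near-identical copies are therefore uncertain. The deposited counts are not normalized.

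The rows for reads given to no gene were kept out of library sizes and tests. Reads that were not aligned made up 42.0% to 51.8% of all reads of a library, reads aligned to more than one place 5.56% to 7.18%, reads aligned outside gene models (the no-feature share) 10.1% to 13.6%, and reads falling on more than one gene 0.599% to 0.706%. Reads assigned to genes ranged from 7463875 to 9215695 per library. A limit of 3 counts corresponded to 0.326 to 0.402 CPM (gene counts scaled to a common library total). Such floors cover counting error only, since PCR copies of one molecule are not told apart.

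The tables give gene IDs without names. The reference table used here, of the newer assembly GRCr8, matched 0 of the 32662 IDs, so the files do not pair the IDs with names. The 34 gene lists fixed before the data were examined, 15 of them markers of cell types, and a fixed panel of 6 activity-related genes were therefore not tested. A difference in the cell make-up of the punches was not measured for the same reason. The rule for named genes took those with the largest absolute log2 fold change among genes with an adjusted p under 0.05, a mean of at least 1 CPM in the higher group and no overlap between the libraries of both groups. It was applied without its condition on gene names and limited over both regions to 2 IDs that rose and 2 that fell, the latter being the ID that fell most in each region.

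Replicate libraries were first compared with a chi-square statistic over genes. All 18 pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.67 to 4.98, and none was treated as a repeat of another. Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (glmQLFit and glmQLFTest, quasi-likelihood F test, two-sided), with TMM factors, the filterByExpr filter by group and Benjamini-Hochberg adjustment within each comparison. Genes with an adjusted p under 0.05 are referred to as called. Comparisons within a region used its 9 libraries, the third group adding to the estimate of the spread. The difference between regions in the change after training and the difference between naive regions used all 18 libraries. Standard errors of log2 fold changes were derived from the F statistic. Intervals are at 95%. Gene sets were tested with camera of limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and with an estimated one, and with fry. Overlaps of calls were tested with Fisher's exact test, two-sided.

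The 1 h and 6 d comparisons share the naive libraries. To give the covariance expected without any effect, all libraries of a region, the naive ones included, were simulated from a common mean per gene, with each gene drawn independently. The tests were tried on simulated counts in which a seeded set of genes was changed. For PL at 1 h, edgeR recovered 54.5% of genes changed 1.41-fold, 93.9% of those changed 2-fold and 98.5% of those changed 4-fold, over 14177 genes. For dHC at 1 h it recovered 74.6%, 86.6% and 95.5% over 14174 genes. For dHC at 6 d the shares were 53.7%, 90.9% and 95.5% over 14186 genes, and for PL at 6 d 62.7%, 89.4% and 98.5% over 14198 genes. For the regional difference at 1 h they were 33.3%, 76.1% and 98.5% over 14587 genes, and at 6 d 33.3%, 69.7% and 86.4% over 14581 genes. False calls made up 2.82% to 9.19% of the calls of a simulated comparison. Each share of recovered genes rests on 65 to 67 changed genes in a single draw. The simulated comparisons called 180 genes in dHC at 1 h, 173 in dHC and 176 in PL at 6 d, and 142 for the regional difference at 1 h. Fewer genes were called there in the data, which makes the adjusted threshold harder to pass. The shares are therefore not the power of those comparisons in the data.

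Alternatives set before the data were examined were DESeq2 1.42.0, RLE size factors, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, a term for the replicate number, only the 2 groups compared, all 18 libraries in one fit, and leaving out each library in turn. Limma voom, voom with a weight per group, and the no-feature share among uniquely aligned reads as a covariate were added after seeing the data. Python 3.11.15 with matplotlib 3.10.9 drew the plots.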

Results

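Transcript levels were measured by RNA sequencing in dHC and PL of rats that were naive, or had been trained in inhibitory avoidance 1 h or 6 d before. Each of the 6 groups held 3 pools of 5 rats. Total gene counts per library ran from 7687831 to 8874826 in naive dHC, 8914752 to 9136114 in dHC at 1 h and 7921311 to 8806419 in dHC at 6 d. In PL they ran from 8145006 to 9215695 in naive pools, 8509697 to 8887687 at 1 h and 7463875 to 9081537 at 6 d. Between 17823 and 18294 genes had at least 1 count in a library. The 24 comparisons of depth and read assignment between groups gave no exact permutation p under 0.1, the smallest that 3 pools against 3 allow. At that limit, dHC pools at 1 h were all deeper than the naive and the 6 d dHC pools. PL pools at 6 d all had a higher share of reads outside gene models than PL pools at 1 h, with means of 12.8% and 11.6% (p = 0.1, adjusted p = 0.6 over the 24 tests, two-sided exact permutation test).

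The first question was how far the regions differ without training. Of 14784 genes tested in naive rats, 6839 were called by edgeR, 3384 of them higher in dHC and 3455 higher in PL. More than 2-fold differences were found for 893 genes higher in dHC and 867 higher in PL. The median log2 difference was 0.64 among genes higher in dHC and −0.52 among genes higher in PL. The first principal component over all 18 libraries held 72.2% of the variance and placed every dHC library between 43.4 and 44.5 and every PL library between −46.8 and −41.5, so that each library lay with its labelled region.

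**Figure D1:**
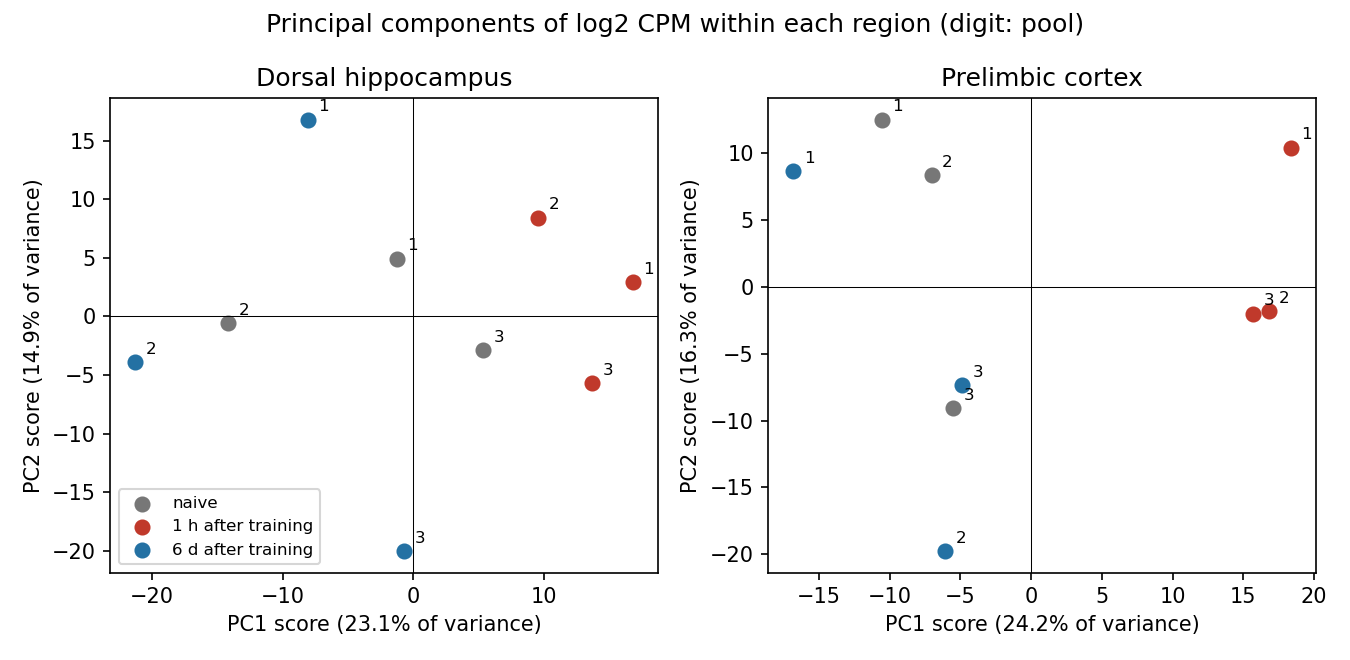
Scores of the 9 libraries of each region on the first and second principal components of log2 CPM (arbitrary units), coloured by condition, with the pool number beside each point. In PL the 1 h pools lay at 15.7 to 18.4 on PC1 and all other pools at or below −4.87. In dHC the 1 h pools lay at 9.60 to 16.8 and the naive pools at −14.2 to 5.33.

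In PL, 1 h after training, 112 genes were higher and 94 lower than in naive rats, of 14318 tested. The called genes that rose had a median log2 fold change of 0.70 and those that fell a median of −0.48. A change of more than 2-fold was seen in 24 genes that rose and in 3 that fell. The gene that rose most was ENSRNOG00000000640, from 3.52 ± 0.777 CPM in naive PL (SD, n = 3) to 47.2 ± 3.22 CPM at 1 h, a log2 fold change of 3.73 (SE 0.18, edgeR adjusted p = 4.11e-12). ENSRNOG00000008015 rose from 6.88 ± 2.48 to 57.1 ± 5.10 CPM, a log2 fold change of 3.06 (SE 0.16, edgeR adjusted p = 1.09e-11). The gene that fell most, ENSRNOG00000037931, went from 3.34 ± 0.850 to 1.15 ± 0.285 CPM, a log2 fold change of −1.53 (SE 0.31, edgeR adjusted p = 0.0119). It had only 7 to 12 counts per library at 1 h, and its adjusted p was 0.0918 without 1 h pool 2 and 0.118 without naive pool 1, in a range of 0.000310 to 0.118 over 18 alternatives. The count rose to 546 with only these groups in the fit, to 564 without a filter on low counts, to 522 with the no-feature share as covariate and to 574 without 6 d pool 1. In these fits fewer genes were higher than lower (249 and 297, 255 and 309, 207 and 315, 251 and 323), as with a term for the replicate number (153 and 159) and without naive pool 3 (89 and 154). It fell to 98, 89 and 87 without 1 h pools 1, 2 and 3, and to 92 and 98 without naive pools 1 and 2.

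In dHC, 1 h after training, 31 genes were higher and 1 lower than in naive rats, of 14305 tested. The median log2 fold change of the genes that rose was 0.52, and 4 of them rose more than 2-fold. ENSRNOG00000000640 was again the gene that rose most, from 0.673 ± 0.111 CPM in naive dHC (SD, n = 3) to 5.87 ± 0.655 CPM at 1 h, a log2 fold change of 3.11 (SE 0.29, edgeR adjusted p = 1.37e-05). It had only 5 to 6 counts per library in naive dHC and 46 to 58 at 1 h. ENSRNOG00000008015 rose from 2.76 ± 0.485 to 7.87 ± 0.730 CPM, a log2 fold change of 1.49 (SE 0.21, edgeR adjusted p = 0.0013). The gene called lower, ENSRNOG00000019358, went from 9.16 ± 0.129 to 2.94 ± 0.788 CPM, a log2 fold change of −1.64 (SE 0.31, edgeR adjusted p = 0.0253). Its adjusted p lay between 0.0703 and 0.255 when any one of the naive or 1 h pools was left out, in a range of 1.09e-11 to 0.255 over 18 alternatives. The count rose to 58 with DESeq2, to 98 genes higher and 30 lower with only these groups in the fit, to 180 higher and 95 lower without a filter on low counts, to 84 higher and 71 lower with the no-feature share as covariate, to 110 higher and 40 lower with a term for the replicate number, and to 50 with all 18 libraries and 81 with a weight per group, and to 60 and 66 without 6 d pools 2 and 3. It fell to 14 and 17 without 1 h pools 1 and 3 and to 15 without naive pool 1.

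**Figure D2:**
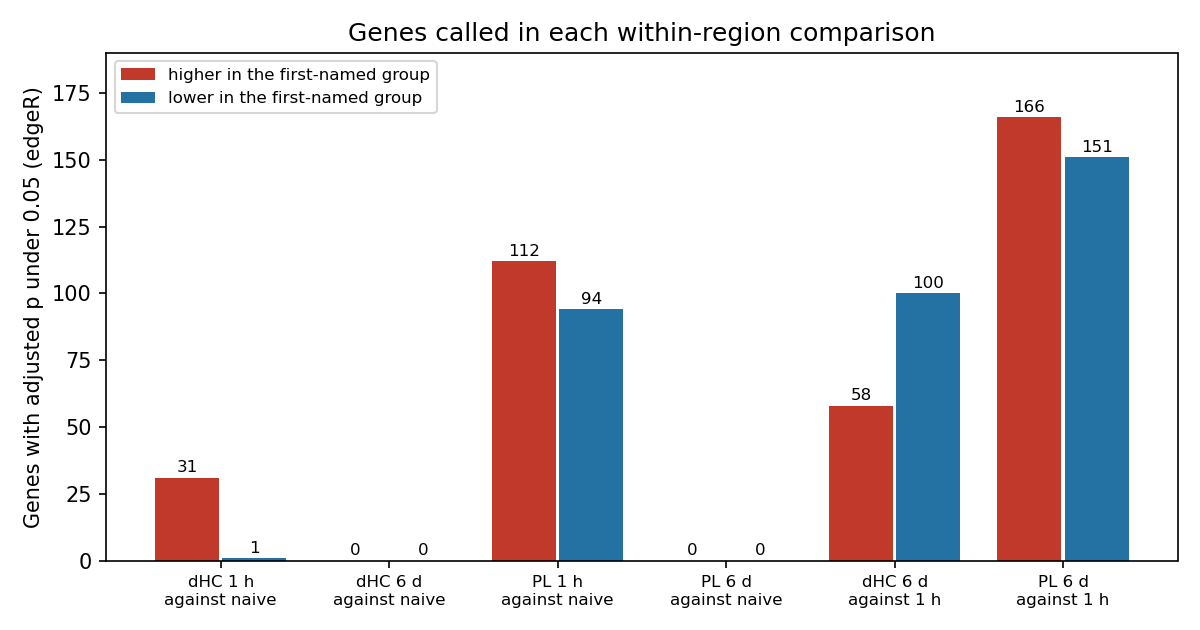
Number of genes with an edgeR adjusted p under 0.05 in each comparison within a region, split by direction relative to the first-named group. The bars show 112 genes higher and 94 lower in PL at 1 h, 31 and 1 in dHC at 1 h, and 0 in either region at 6 d against naive.

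The genes called at 1 h were then compared between the regions. Among 13905 genes tested in both, 15 were higher at 1 h in both regions, where 31 and 111 calls would share 0.247 if independent (Fisher's exact p = 3.45e-24, adjusted p = 6.91e-24 over 10 overlaps, a description of these gene lists, since genes are not independent replicates). No gene was called lower in both, where 1 call in dHC and 93 in PL would share 0.00669 if independent, so nothing follows from this count. Of the 15 shared genes, 14 had the larger log2 fold change in PL, with medians of 1.20 in PL and 0.84 in dHC. The overlap was 44 genes without a filter on low counts and 26 with only the groups compared in each fit. The 111 genes higher in PL and tested in dHC had a median log2 fold change of 0.25 in dHC, with 99 above 0 (camera adjusted p = 0.000446 with an estimated correlation). The 93 genes lower in PL had a median of −0.14 in dHC, with 82 below 0, and 0 of them were called there by edgeR. As a set they passed with the preset correlation (camera adjusted p = 1.87e-12) but not with an estimated one (adjusted p = 0.219 with an estimated correlation). The 31 genes higher in dHC had a median of 0.14 in PL, with 25 above 0 (camera adjusted p = 0.00504 with an estimated correlation).

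The test of the regional difference itself called 14 of 14784 genes at 1 h. For 9 of them the change was more positive in PL, and for 5 more positive in dHC. The 9 genes more positive in PL were all among the genes called higher there. Of the genes called in dHC, 6 passed this test, 3 with the larger rise in PL and 3 with the larger rise in dHC. ENSRNOG00000008015 differed by −1.56 in log2 fold change, dHC minus PL (SE 0.31, edgeR adjusted p = 0.0327). This call was lost without PL 1 h pool 1 or 3, PL naive pool 1 or 2, dHC 1 h pool 1 or 2, or dHC naive pool 1 or 3, with adjusted p between 0.0573 and 0.321. For ENSRNOG00000000640 the difference of −0.62 did not pass (SE 0.50, edgeR adjusted p = 0.810). The fall of ENSRNOG00000019358 in dHC was set against 0.44 in PL (SE 0.29), and the difference of −2.07 did not pass (SE 0.49, edgeR adjusted p = 0.136), though it did with DESeq2 (adjusted p = 0.0313), with a weight per group and with a term for the replicate number (adjusted p = 0.0495 each), without a filter on low counts (adjusted p = 5.93e-06) and without 6 d pool 1 or 2 of dHC (adjusted p = 0.00696 and 0.0354). Over 26 alternatives this adjusted p ran from 5.93e-06 to 0.442. The count of 14 rose to 22 with DESeq2 and with a weight per group, to 37 with the no-feature share as covariate, to 117 without a filter on low counts and to 27 without PL naive pool 3. It fell to 6 without dHC 1 h pool 1, to 7 without dHC naive pool 1, PL 1 h pool 1 or PL naive pool 1, and to 9 without PL naive pool 2. More of the genes were more positive in dHC than in PL without a filter on low counts (75 and 42) and without PL naive pool 3 (17 and 10). The same held without dHC naive pool 3 (9 and 7) or dHC 1 h pool 2 (9 and 8). In the other alternatives more were more positive in PL.

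**Figure D3:**
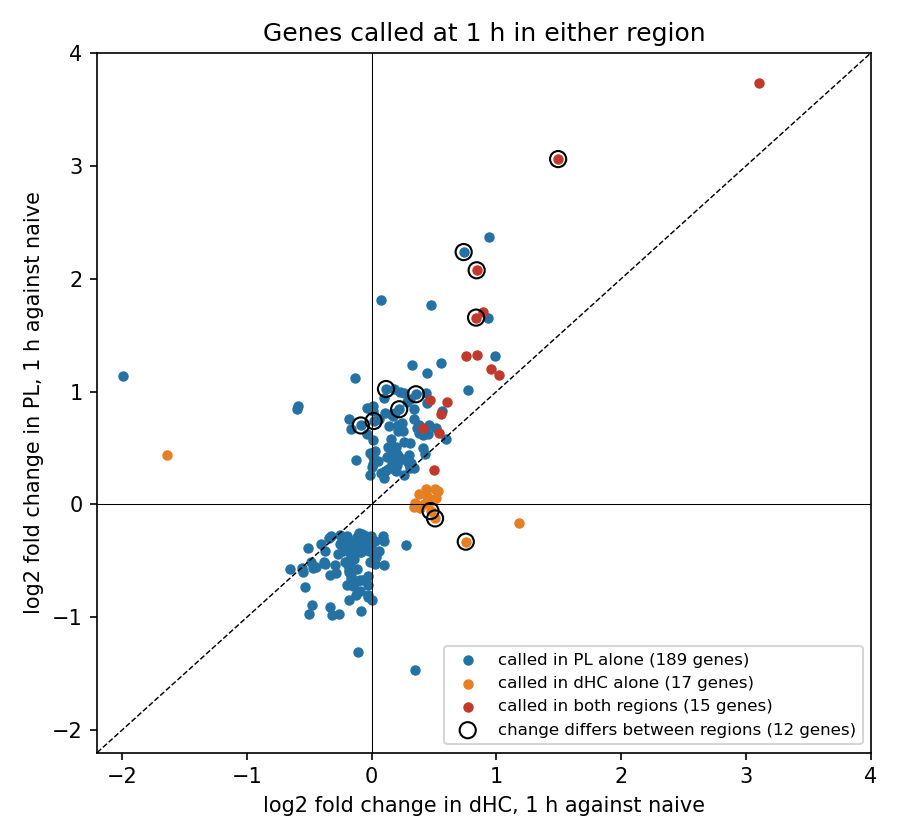
Log2 fold change at 1 h against naive in dHC (horizontal) and PL (vertical) for genes called in either region and tested in both, with the line of equal change dashed. The 15 genes called in both regions lie in the upper right, 14 of them above the line, and 12 genes whose change differed between the regions by the test of that difference are ringed.

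At 6 d after training, 0 genes were called against naive in either region. In dHC, 804 of 14305 genes had an unadjusted p under 0.05, where 715 would by chance, and the smallest edgeR adjusted p was 0.437. With each library left out in turn this number ran from 572 (without naive pool 1) to 1169 (without 6 d pool 3). In PL the number was 497 of 14318, where 716 would by chance, and the smallest edgeR adjusted p was 0.999. It rose above chance to 1565 without 6 d pool 1 and to 922 without naive pool 3, with 0 and 1 genes called. The split of the PL pools in which these 2 pools change places, the highest of the 9 other splits, called 720 genes by edgeR. DESeq2 called 1 gene in dHC and 0 in PL, limma voom 0 in both, with 423, 218, 804 and 494 genes at an unadjusted p under 0.05, the fit without a filter on low counts 31 in dHC and 8 in PL, and the fit with a term for the replicate number 3 in dHC and 0 in PL. Leaving out one library gave 1 gene in dHC without 6 d pool 1 and 1 without naive pool 2, and 1 in PL without naive pool 3. The 95% interval of the 6 d change lay within a log2 change of 1 in either direction for 93.4% of the genes in each region, and within 0.5 for 72.2% in dHC and 73.3% in PL. ENSRNOG00000000640 had 0.565 ± 0.186 CPM in dHC and 4.22 ± 1.89 CPM in PL at 6 d (SD, n = 3), with log2 fold changes of −0.24 (SE 0.47) and 0.23 (SE 0.27) against naive. In dHC it had only 3 to 6 counts per library at 6 d, near the limit of 3 counts. ENSRNOG00000019358 was at 4.55 ± 3.22 CPM in dHC at 6 d, a log2 fold change of −1.02 against naive (SE 0.29, edgeR adjusted p = 0.831), which passed at −1.76 without 6 d pool 1 (edgeR adjusted p = 0.0136) and at −1.02 without a filter on low counts (edgeR adjusted p = 0.000499). Over 19 alternatives this adjusted p ran from 0.000499 to 0.999. The 1 h and 6 d changes share the naive libraries. Their covariance over genes was 0.00994 in dHC and 0.0112 in PL. Unchanged groups sharing a likewise simulated naive group gave 0.0145 in dHC and 0.0140 in PL. Each gene was simulated on its own. The simulations therefore do not show how far the covariance can lie from these values without any effect when genes vary together. The correlation over genes, which are not independent replicates, was 0.286 in dHC and 0.296 in PL, against simulated values of 0.501 and 0.498, and the share of genes changed in the same direction was 59.7% and 60.8%, against 66.7% and 66.6%. In PL the covariance exceeded its simulated value by 0.00233 without 6 d pool 1 and by 0.00254 without naive pool 3. The test of the regional difference at 6 d called 0 of 14784 genes with edgeR, DESeq2 and limma voom, and 12 without a filter on low counts. With edgeR, 558 genes had an unadjusted p under 0.05, where 739 would by chance, but 1126 without PL 6 d pool 1 and 823 without dHC 6 d pool 1.

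The genes that had changed at 1 h were followed to 6 d. The 112 genes higher in PL at 1 h had a median log2 fold change of −0.00 against naive at 6 d, and the 94 lower ones a median of −0.06. The 31 genes higher in dHC had a median of 0.09, in a range of −0.32 to 0.51. Of these 31, 8 had an unadjusted edgeR p under 0.05 at 6 d against naive, as did 5.62% of all dHC genes tested. In PL 9 of the 112 and 9 of the 94 did, and 3.47% of all genes tested. None of these genes was called at 6 d. The shared naive libraries by themselves favour a 6 d change in the direction seen at 1 h. Compared directly with 1 h, 166 genes were higher and 151 lower in PL at 6 d, and 58 were higher and 100 lower in dHC. In PL fewer were higher than lower without 1 h pool 1 (49 and 102) or 1 h pool 2 (61 and 88). The same held without 1 h pool 3 or 6 d pool 3, and with DESeq2 or limma voom. With all 18 libraries in one fit they were 112 and 144, and in the other PL alternatives more were higher. In dHC more were lower in every alternative. The counts there ran from 2 higher and 16 lower without 1 h pool 3 to 299 and 324 without a filter on low counts. They were most even without 6 d pool 1 (116 and 120). Among the genes called against 1 h were 82 of the 112 that had risen in PL, called lower again. They included 54 of the 94 that had fallen in PL, called higher again. In dHC they included 21 of the 31 that had risen, called lower again. Both comparisons use the 1 h libraries, which by itself favours such overlaps. In 5 simulations per region, unchanged groups sharing simulated 1 h libraries had on average 0.2 such genes in dHC and 0 in PL. With only 0.6 and 0 genes called at 1 h, these simulations do not show what sharing brings to longer lists. ENSRNOG00000000640 differed by −3.50 between 6 d and 1 h in PL (SE 0.18, edgeR adjusted p = 6.27e-12) and by −3.34 in dHC (SE 0.30, edgeR adjusted p = 8.32e-06).

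The direct comparison of 6 d with 1 h called 317 genes in PL and 158 in dHC, where 1 h against naive called 206 and 32. The order reversed in PL with only the groups compared (297 against 546), with the no-feature share as covariate (209 against 522), without 6 d pool 1 (324 against 574) and without 6 d pool 2 (224 against 236), and in dHC without 6 d pool 2 (40 against 60). Leaving out a 6 d pool makes a compared group smaller only for 6 d against 1 h. In PL the count was 675 without a filter on low counts, 209 with the no-feature share as covariate, and 151, 149 and 190 without 1 h pools 1, 2 and 3, and the 82 genes called lower again were 164 without a filter, 48 and 45 without 1 h pools 2 and 3 and 53 without naive pool 2, and the 54 called higher again were 170 without a filter, 86 with only the groups compared, 30 with all 18 libraries, 104 with the covariate, 19, 18 and 24 without 1 h pools 1, 2 and 3 and 26 and 33 without naive pools 1 and 2. In dHC the count was 623 without a filter, 494 with the covariate, 29 and 18 without 1 h pools 1 and 3, 40 without 6 d pool 2 and 343 without 6 d pool 3, and the 21 genes called lower again were 33 with DESeq2, 117 without a filter, 32 with only the groups compared, 62 with the covariate, 10 and 12 without 1 h pools 1 and 3 and 13 without naive pool 1.

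**Figure D4:**
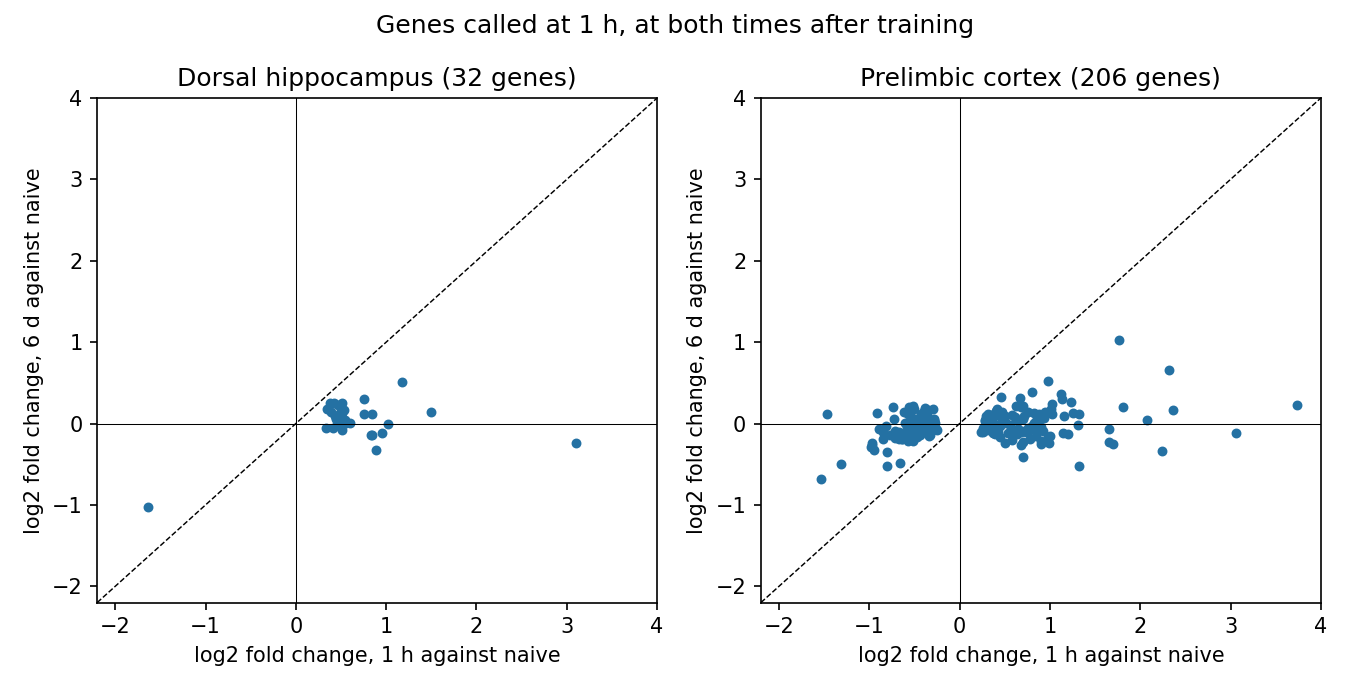
Log2 fold change at 6 d (vertical) and 1 h (horizontal), both against naive, for the 32 genes called at 1 h in dHC and the 206 called at 1 h in PL, with the line of equal change dashed. At 6 d the medians lie at 0.09 for genes that had risen in dHC and at −0.00 and −0.06 for genes that had risen and fallen in PL. Both axes share the naive libraries.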

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

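The counts over other splits of the pools, the test of whether folds of the size seen in PL would pass in dHC and the test of calls by level were set before their results were seen. The other tests of explanations in this part were chosen after.

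A difference between the regions singled out 14 genes whose 1 h change was not the same in dHC and PL, and among the genes given by ID it singled out ENSRNOG00000008015, with a difference of −1.56 in log2 fold change, dHC minus PL. For this gene the edgeR adjusted p of 0.0327 rose to between 0.0573 and 0.321 (range over 26 alternatives 3.00e-06 to 0.321) without PL 1 h pool 1 or 3, PL naive pool 1 or 2, dHC 1 h pool 1 or 2, or dHC naive pool 1 or 3. The splits of the pools within each region that were tested were 40, the real one and a random sample of all others. Of these 40, 5 called at least 14 genes, the real one included, and the highest of the others called 52, so chance is not excluded by this count. The 4 other splits kept the PL 1 h pools apart from the PL naive pools, 2 of them with the PL labels reversed, and mixed the dHC pools, so that they still held the PL change, while the 35 splits that mixed the PL pools called 0 genes.

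More genes were called at 1 h in PL than in dHC. A larger spread of the typical gene between dHC pools is argued against by the ratio of median standard errors, dHC over PL, of 0.992. This median over all tested genes does not show spread that many genes share. On the first principal component of each region, the naive pools had an SD of 9.92 in dHC and 2.57 in PL. The 1 h pools had an SD of 3.63 in dHC and 1.34 in PL. The components were fitted separately by region, so their scores are not on one axis. Whether spread along the 1 h change cost calls in dHC therefore stays open. A lower level of the responding genes in dHC is argued against by their median log2 difference at 6 d, dHC minus PL, of 0.22. It lay above the range of −0.08 to 0.08 of random lists. Some of the responding genes were lower in dHC, with 24 called higher in PL at 6 d and 49 higher in dHC. Both IDs that rose were lower in naive dHC (−2.39 for ENSRNOG00000000640 and −1.30 for ENSRNOG00000008015). The 24 were nonetheless called in dHC at 1 h more often (9 of 24) than the 49 (6 of 49, Fisher's exact p = 0.0278 over genes, which are not independent replicates). The size of their rise was not held equal, so this count does not decide whether a lower level cost them calls in dHC. At the lower 95% bound of their PL fold, 25 of 111 genes would pass in dHC. This count met the limit set beforehand for folds of the size seen in PL being too small to pass in dHC. Only 34 would pass in PL itself, however, which that limit did not take into account. Whether folds of the size seen in PL would pass in dHC therefore stays open. Whether the same genes moved less in dHC stays open too. Genes chosen by their call in PL favour PL in the test of the regional difference, which uses the same libraries. Genes chosen by their call in dHC favour dHC in it for the same reason. Of the genes called higher in dHC that passed it, 3 had the larger change in PL and 3 in dHC, so this count is not neutral between the regions. The 3 pools against 3 make 10 splits, too few for a share under 0.05, and the real splits called 206 genes in PL and 32 in dHC, where the highest of the others called 0 in each.

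In each region more genes separated 6 d from 1 h than 1 h from naive, by a ratio of 4.94 in dHC and 1.54 in PL, an order that reversed in dHC without 6 d pool 2 (40 against 60 genes) and in PL without 6 d pool 1 (324 against 574) or 6 d pool 2 (224 against 236). These omissions make a compared group smaller only for 6 d against 1 h, so both counts are not set at equal power. A spread that differs between the groups sharing one fit remains a candidate explanation in PL, where the ratio was 0.544 with only the groups compared in each fit and 1.14 with a weight per group. In dHC it stays open, because the ratio was 1.29 with only the groups compared but 1.80 with a weight per group. The no-feature share as covariate left a ratio of 3.19 in dHC, which argues against it there, and gave 0.400 in PL, where the 6 d and 1 h pools do not overlap in that share and only 104 of the 317 calls were kept. A shift of the 6 d pools from naive away from the 1 h pools, biological or not, stays open in dHC, where the covariance of both changes lay below its simulated value by −0.00460 and was below it with each of the 9 libraries left out (−0.00698 to −0.00150), while in PL the value of −0.00281 cannot be told apart from no shift, being 0.00233 without 6 d pool 1 and 0.00254 without naive pool 3. The 10 splits are too few for a share under 0.05, with 158 genes in dHC and a highest other of 1, and 317 in PL and a highest other of 0.

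Another split of the PL naive and 6 d pools, 6 d pool 1 with naive pools 1 and 2 against the remaining 3, called 720 genes, where the real split called 0, which points to a structure of the samples that the labels do not give. This is the split that exchanging the labels of 6 d pool 1 and naive pool 3 would give. Such an exchange stays open, since both pools lay nearer to the other group than to their own, with ratios of the distances (root mean square difference in log2 CPM over 8567 genes) of 0.736 for 6 d pool 1 and 0.857 for naive pool 3. Any structure that parts the pools in this way would give such ratios, and no value separates it from an exchange. If the labels were exchanged, the count of 0 genes at 6 d in PL would not describe the effect of training. The other PL comparisons and the regional differences use these pools too and would also be affected. Without naive pool 3, PL at 1 h had 89 genes higher and 154 lower, and 140 of the 206 calls were kept. Library depth is argued against as its source, since the highest of the other splits still called 661 genes after all libraries were thinned to the 7463875 counts of the smallest. With the no-feature share as covariate the highest count was 131. That share of uniquely aligned reads does not overlap between both sides of this split, with 24.5% to 25.8% against 26.5% to 27.8%. Such a covariate takes calls away whatever their source, so whether that share has a part in this structure stays open. No biological explanation was tested, because the split crosses the groups as labelled. In dHC the real split of naive and 6 d pools called 0 genes and the highest of the others 43 among 10 splits, too few for a share under 0.05 in either region.

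For the regional difference at 6 d, 40 splits were tested, again the real one and a random sample of all others. The real split called 0 genes, so that all 40 splits call at least as many by construction and nothing follows about chance. The highest of the others called 163, which points to a structure of the samples here too. For the naive regions, the real split called 6839 genes and the highest of the others 0, among 10 splits that are too few for a share under 0.05.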

How the results depend on the processing

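The tests with limma voom, a weight per group and the no-feature covariate, the alternatives for sets of genes and for calls shared by comparisons were chosen after seeing the data. Among the genes called in each comparison, 1 of the 6839 called between naive regions changed sign, without dHC naive pool 1, and 0 in the other comparisons or alternatives. No called gene given by ID changed sign. With RLE size factors and with the filter of 1 CPM in 3 libraries, which kept more genes than filterByExpr, the counts of called genes stayed within 1.5 times. Where a count moved more, the cause was not tested. The numbers called in dHC at 1 h (32), PL at 1 h (206), dHC at 6 d against 1 h (158), PL at 6 d against 1 h (317) and for the regional difference at 1 h (14) became 275, 564, 623, 675 and 117 with no filter on low counts. With no filter, the counts of 0 at 6 d against naive became 31 in dHC and 8 in PL, that of the regional difference at 6 d 12, and the overlap of 15 genes higher at 1 h in both regions 44. DESeq2 gave 58 in dHC at 1 h, 1 in dHC at 6 d and 22 for the regional difference at 1 h. Only the 2 groups compared gave 1.3e+02 (98 higher and 30 lower) in dHC and 546 in PL at 1 h, with an overlap of 26. All 18 libraries in one fit gave 50 in dHC at 1 h. A weight per group gave 81 in dHC at 1 h and 22 for the regional difference. The no-feature share as covariate gave 155 in dHC and 522 in PL at 1 h, 494 in dHC and 209 in PL at 6 d against 1 h, and 37 for the regional difference.

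With each library left out in turn, the count ranged from 14 (without 1 h pool 1) to 66 (without 6 d pool 3) in dHC at 1 h, 0 to 1 in dHC at 6 d (1 without 6 d pool 1 or naive pool 2), 87 (without 1 h pool 3) to 574 (without 6 d pool 1) in PL at 1 h, 0 to 1 in PL at 6 d (1 without naive pool 3), 18 (without 1 h pool 3) to 343 (without 6 d pool 3) in dHC at 6 d against 1 h, 149 (without 1 h pool 2) to 358 in PL at 6 d against 1 h, 6 (without dHC 1 h pool 1) to 27 (without PL naive pool 3) for the regional difference at 1 h, 0 to 0 at 6 d, and 6107 to 6997 for the naive regions. The overlap at 1 h ranged from 10 to 18. The excess covariance of the 1 h and 6 d changes was −0.00460 in dHC, ranging from −0.00698 to −0.00150, and −0.00216 with no filter. In PL it was −0.00281, ranging from −0.00494 to 0.00254, with the positive values of 0.00233 without 6 d pool 1 and 0.00254 without naive pool 3, and −0.00211 with no filter. The median voom value in dHC at 1 h of the genes lower in PL, −0.14, ranged from −0.18 to −0.10, and its camera p of 1.25e-12 became 0.146 with an estimated correlation. The medians of the genes higher in PL, tested in dHC, ranged from 0.22 to 0.26, and of those higher in dHC, tested in PL, from 0.12 to 0.28, with every p past the threshold.

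The replicate numbers were not taken to pair the pools: the correlation of same-numbered pools' deviations ran from −0.0604 to 0.205 between conditions of a region and from −0.122 to 0.0390 between regions, 0 of 9 sets of numbers had all correlations over 0.1, and 8 of 18 and 3 of 9 pools correlated best with their own. In dHC at 6 d and naive all 3 did (0.0530, 0.205 and 0.159). With the replicate block the calls were 150 in dHC at 1 h, 3 in dHC at 6 d, 312 in PL at 1 h, 0 in PL at 6 d, 549 in dHC and 423 in PL at 6 d against 1 h, 23 and 0 for the regional difference at 1 h and 6 d, 5960 for the naive regions, and 27 in the overlap. The alternatives for the gene lists were not run, as IDs were not paired with names. Of the remaining values, 9 of single genes gained and 21 lost a call and 859 kept their side, and of the others 72 rose and 48 fell past their limit, 1 moved and 329 stayed. Changes of weakly expressed genes were measured less precisely. In the lowest of 4 expression classes the median SE of log2 fold changes was 0.278 in PL at 1 h, against 0.0678 in the highest. Of the 206 calls, 23 fell in the lowest class. Whether depth limits such calls was not tested.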

Other observations

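The level of the genes that rose in PL at 1 h was compared between the regions in the 6 d libraries, which took no part in choosing them except through the shared estimate of the spread. Before the result was seen, the hypothesis was that genes which rise in PL have a higher resting level in PL than in dHC. The opposite was measured: the median log2 difference, dHC minus PL, of these 112 genes at 6 d was 0.22, above all of 10000 random lists matched on mean expression, whose central 95% ran from −0.08 to 0.08. Genes of the random lists were drawn one by one. Their range therefore leaves out correlation between genes and the spread between pools, and describes this gene list only. By edgeR, 49 of them were called higher in dHC at 6 d and 24 higher in PL. The median ranged from 0.17 to 0.24 over 9 alternatives chosen after seeing the data, including leaving out each 6 d library. The 94 genes that fell in PL had a median of −0.04, at percentile 32.8 of their random lists, and the 31 genes that rose in dHC a median of −0.08, at percentile 20.5.

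The spread between pools was compared between the groups. Over 8606 genes with more than 16 CPM in dHC, the root mean square SD of log2 CPM between pools was 0.107 at 1 h, 0.113 in naive rats and 0.136 at 6 d. With any 1 pool of a group left out, the 6 d value in dHC was at least 0.132, above every naive (0.109 to 0.116) and 1 h value (0.106 to 0.108). Over 8567 such genes in PL it was 0.105, 0.112 and 0.128, an order that rests on single pools: the 6 d value was 0.101 without pool 1, the naive value 0.0996 without pool 3 and the 1 h value 0.0900 without pool 1, and the 1 h value was 0.110 and 0.114 without pools 2 and 3. With 3 pools per group no test of these spreads was made. The 93 genes that had fallen in PL and were tested in dHC varied together among the dHC pools, with an estimated correlation between genes of 0.369, against 0.0208 for the 111 genes that had risen in PL.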
